A study of Mus musculus with 8 samples.

How the data were processed

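Messenger RNA was measured in whole hearts of C57Bl/6 mice aged 8 to 10 weeks, per the labels. In 4 mice a branch of the left coronary artery had been tied off permanently. Another 4 mice had a sham operation in which the suture was passed without being tied. Each heart was hybridised to its own spotted array of 70-mer oligonucleotides. The heart RNA carried the red dye and a pooled reference RNA of adult mouse tissues the green dye on every array, per the labels. Each dye had 30 µg of RNA, and no dyes were swapped. The labels give no scan date, print run or slide batch. The time between ligation and tissue collection was not given in the sources used here.

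The deposited table holds log2 values for 33600 spots on 8 arrays. A ratio of heart to reference had been assumed when the tests were fixed, but the values are of another kind. Within each of 48 blocks of 700 consecutive spots, every deposited value became a whole number, within a tolerance of 0.001, when 2 to the power of the value was multiplied by 1 constant per block and array. The recovered signals ran from 42 to 65466, just under the 65536 steps of a 16-bit scanner image. Each block on each array had a median of 0, and so did each of the 8 array columns. The deposited log2 values are therefore read here as the signal of 1 channel divided by the median signal of the spot's block, with the other channel absent. Genes of the heart muscle lay far above the median on the sham arrays. The reference pool held heart RNA too, so this does not settle which channel the values hold. The heart channel is assumed below. The submitters' software, background correction and spot flags were not given in the sources used here, and whether the signals were background-subtracted stays unknown. A fold change below is a difference between groups of this block-scaled signal. The tests fixed beforehand were run on this signal unchanged. With 1 channel alone, a difference in a spot between arrays is not divided out by the reference.

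Spots without a value numbered between 8781 and 13896 per array, and 6147 spots had no value on any array. Both very dim and very bright spots were affected. Among features whose signal exceeded 20000 on at least 1 array, 155 values were missing on the sham arrays and 34 on the infarcted arrays. No floor or ceiling was filled in, and no fold is given for a feature without values in 1 group. For arrays, the number of samples limits the precision.

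Probes were named through the platform annotation table supplied with the values. Of the 33600 probes, 18179 had 1 gene symbol, 87 had several, and 15334 were not listed there and are unnamed here. The Entrez identifiers of 18164 probes were found in a RefSeq gene table of assembly GRCm38.p6, used for names alone, and 0 symbols needed an update. A feature was a gene with 1 symbol, averaged over its probes on each array, or otherwise a single probe. Of 13661 such genes, 2663 had more than 1 probe.

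Each array was centred on its median, which changed nothing because the deposited medians were already 0. Features with a value on at least 3 of the 4 arrays of each group were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all 18044 features, and an adjusted p under 0.05 counted as a change. Fold changes are infarcted minus sham control, with the standard error (SE) of the fit. Because the RNA came from separate hearts per the labels, p-values measure the spread between these hearts together with that of the arrays. The replicate arrays were not copies of each other, since the correlation across features between any 2 arrays of a group was at most 0.952.

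In addition, 41 gene lists fixed before the data were examined were tested with limma's camera method on the moderated statistics (cameraPR, which accepts missing values). The preset correlation between genes was 0.01, and Benjamini-Hochberg adjustment ran over the 40 lists with at least 5 tested members. The list of sex-linked genes had 2 tested members and was not tested. Beside it stand camera with an estimated correlation and the rotation test fry, both on features with a value on all 8 arrays. An exact two-sided permutation test compared the list's mean per array over all assignments of the 8 arrays, and its smallest possible p is 0.0286. Members were also counted with p-values adjusted over the list alone. The median of each list was set against 10000 random lists of the same size and signal level.

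Genes were named by a rule fixed before the data were examined. It took the 12 largest increases and the 12 largest decreases past the threshold whose groups did not overlap, or fewer where fewer passed. It added up to 4 members of each list that passed, with the smallest p in the list's direction, and up to 2 changed members of each list that did not. Another 16 genes were fixed by name, and clone-like names were left out. The alternatives fixed beforehand included no centring, quantile and scale normalization, other filters on missing values, 1 probe per gene and array weights. They also included the replicate number as a block, leaving out each array, robust eBayes, an unequal-variance test per feature, rules with a fold of 1.5 and an unadjusted p, an adjusted p under 0.10, and leaving out the lowest and highest 1% of values. After the data were seen, loess against the mean array, a whole-array median in place of block medians, and removal of the position effect within blocks were added. A signal minimum of 200, averaging only probes complete on 8 arrays, and leaving out the 2 sham arrays with the fewest values were added as well.

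The fit was tested on simulated data with the sham means, the moderated spread of the fit and the real missing values. In these data 200 of 18044 features were changed. Of the features changed by 1 on the log2 scale, 5.71% were recovered, against 79.4% of those changed by 2 and 97.0% of those changed by 3, with 3 false calls. In a second simulation all 3 lists moved by 0.5 were called, and 0 of 37 unmoved lists. Both simulations drew features independently of each other and held no shift with signal level. Their false calls therefore do not cover such a shift or features that vary together. Figures and summary tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.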

Results

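Transcript levels were compared between 4 whole hearts with a permanent coronary ligation and 4 hearts of sham-operated mice, to ask how the heart's transcripts differ in a model of heart failure after ischaemia. Values were present for 19704 to 24819 of 33600 spots on the sham control arrays and for 21916 to 23655 on the infarcted arrays. All levels are log2 signals relative to the median of the spot's block on the array, so 0 is the median spot of a block. In the sham hearts, genes of the adult sarcomere, the contractile unit of heart muscle, had a mean level of 4.90 ± 0.18 (SD, n = 4 arrays, 17 genes with a value).

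A small set of genes that included secreted and immune factors had higher signals on the infarcted arrays. Ccl8, a chemokine that attracts monocytes, rose from -1.22 ± 0.55 to 1.53 ± 0.52 (SD, n = 4 each), a log2 fold change of 2.74 ± 0.35 (SE, limma adjusted p = 0.018). Sfrp2, a secreted modulator of Wnt signalling, rose by 2.48 ± 0.23 (adjusted p = 0.0062). Irak2, a kinase of interleukin-1 receptor signalling, rose by 1.42 ± 0.21 (adjusted p = 0.0306). Its mean level went from -2.01 to -0.59, below the block median in both groups. Cpxm2, a member of the carboxypeptidase family, rose by 1.66 ± 0.27 (adjusted p = 0.0355). The largest increase was that of Tex101, a glycoprotein known from germ cells of the testis, from -0.11 ± 0.47 to 4.74 ± 0.10 (n = 4 each; 28.8-fold, adjusted p = 9.6e-05). Tstd2 rose by 1.46 ± 0.24 (adjusted p = 0.0462), from -2.30 to -0.84, so its mean lay below the block median in both groups. Ccl8, Sfrp2, Tex101 and Tstd2 each rested on 1 probe. For them a difference at that spot between the arrays of the groups stays open. With quantile normalization Irak2, Cpxm2 and Tstd2 kept changes of 1.42 ± 0.23, 1.71 ± 0.29 and 1.32 ± 0.25 but no longer passed (adjusted p = 0.0566, 0.0711 and 0.109).

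Decreases were more numerous. Clpp, the proteolytic subunit of a mitochondrial protease, fell by 3.40 ± 0.31 (SE, adjusted p = 0.0062). Mrpl2, a protein of the mitochondrial ribosome, fell by 3.18 ± 0.33 (adjusted p = 0.01). Dlat, the acetyltransferase of the pyruvate dehydrogenase complex, fell by 3.37 ± 0.45 (adjusted p = 0.0314; 3 values in each group). Ramp2, the partner of the adrenomedullin receptor in endothelium, fell by 3.05 ± 0.31 (adjusted p = 0.01), from 3 sham and 4 infarcted values. Actb, cytoplasmic actin, fell by 1.94 ± 0.21 (adjusted p = 0.01), with all of its 17 probes lower, and its change was -1.45 after quantile normalization (adjusted p = 0.0458). The other large decreases were Nit1 (-3.35, adjusted p = 0.0268), the transcription factor Pax9 (-3.19, adjusted p = 0.0462), Mdfi (-1.86) and 4 genes of odorant or vomeronasal receptors, Olfr136 (-2.88), Olfr575 (-2.27), Vmn1r18 (-2.19) and Olfr1263 (-1.84). With quantile normalization Nit1 and Pax9 stood at -2.81 ± 0.45 and -3.13 ± 0.53 and did not pass (adjusted p = 0.0512 and 0.0853). Of 80 tested genes whose symbols begin with Olfr, 5 passed the threshold, a higher share than the 99 of all 18044 features. The cause was not tested.

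**Figure D1:**
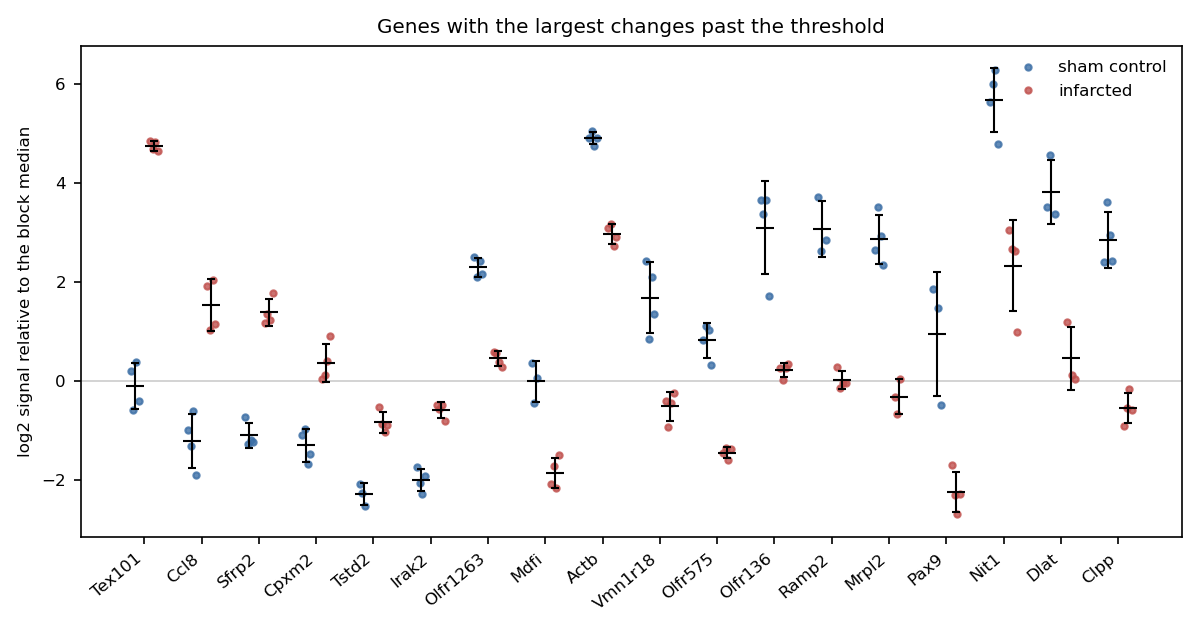
Levels of the 18 genes named by the rule for the largest changes, as log2 signal relative to the block median (y axis), with a point per array (blue, sham control; red, infarcted; 3 or 4 arrays with a value per group) and bars for the mean ± SD. The points of both groups do not overlap for any of these genes, which was a condition for naming them, and Tex101 stands at 4.74 in infarcted hearts against -0.11 in sham hearts.

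In all, 99 of 18044 features changed, 10 higher and 89 lower in infarcted hearts (limma, Benjamini-Hochberg adjusted p under 0.05), among them 6 higher and 31 lower named genes. The groups did not overlap for 8.89% of all features, where chance gives 3.44% on average for the numbers of values present. Features on the same arrays vary together and the share in other splits was not computed, so the excess was not tested. After quantile normalization 5 features were higher and 27 lower, all of them among the 99, and removing the effect of spot position within blocks, an alternative chosen after seeing the data, gave 15 higher and 54 lower. Without sham control replicate 1, 2, 3 or 4 the number of changed features was 25, 37, 28 and 666, and without infarcted replicate 1, 2, 3 or 4 it was 10, 6, 3 and 4.

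Among the gene lists, markers of macrophages and monocytes stood higher in infarcted hearts. Of 21 measured members 17 had a positive fold change, with a mean of 0.49 and a median of 0.49 (camera adjusted p = 3.43e-06). When p-values were adjusted over the list alone 3 members passed, and 0 did so over all features. With an estimated correlation the list did not pass (adjusted p = 0.409). Its leading members were Gpnmb, a glycoprotein of phagocytes, at 1.58 ± 0.31 (SE, adjusted p = 0.06), Ms4a7 at 1.06 ± 0.27 (adjusted p = 0.127), the Fc receptor Fcgr3 at 0.97 ± 0.28 (adjusted p = 0.175) and Adgre1, the F4/80 antigen, at 0.85 ± 0.30 (adjusted p = 0.282). None of these 4 passed on its own. Gpnmb had mean levels of -1.86 in sham and -0.29 in infarcted hearts, below the block median in both.

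Cytokine receptors and their signalling partners were also higher as a list. Of 28 members 22 had a positive fold change, with a mean of 0.33 and a median of 0.32 (camera adjusted p = 9.52e-05), and 0 passed singly, over all features or adjusted over the list alone. With an estimated correlation the adjusted p was 0.439. Members with the smallest p were Osmr, the oncostatin M receptor (0.82 ± 0.23, SE), and Il6st, the signalling subunit shared by receptors of the interleukin-6 family (1.13 ± 0.37). Next came the interleukin-1 receptor Il1r1 (0.86 ± 0.35) and the interferon gamma receptor subunit Ifngr2 (0.69 ± 0.29). None of them passed on its own. Complement and coagulation genes had a mean of 0.29 and a median of 0.13 over 15 members, 11 of them positive (camera adjusted p = 0.0168), and 0 members passed in either adjustment. With an estimated correlation the adjusted p was 0.439, and without sham control replicate 2 or 3 the mean was 0.19 and 0.32 (camera adjusted p = 0.0516 and 0.0594). Leading members were the C1 inhibitor Serping1 (0.65 ± 0.20, and 1.10 after quantile normalization), C4b (1.31 ± 0.42), the coagulation factor F13a1 (0.71 ± 0.24) and Procr (1.22 ± 0.41), for which the probe complete on 8 arrays gave 0.58. All 3 lists kept their camera call after quantile normalization, with means of 0.59, 0.41 and 0.33 in the order given. Loess against the mean array, chosen after seeing the data, left the complement list at a mean of 0.34 and ended its call (adjusted p = 0.0525).

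Lists of energy metabolism in mitochondria were lower with arrays centred on the median. Of 63 genes of oxidative phosphorylation 61 had a negative fold change, with a mean of -0.87 and a median of -0.82 (camera adjusted p = 6.21e-24). The list did not pass with an estimated correlation (adjusted p = 0.409) or after quantile normalization (mean -0.13, adjusted p = 0.302). In this list 5 genes passed over all features and 41 when adjusted over the list alone. Cox7a2 and Cox6b1 of cytochrome c oxidase changed by -1.57 ± 0.24 and -1.29 ± 0.21 (SE, adjusted p = 0.0298 and 0.0337). Atp5j2 of ATP synthase changed by -1.69 ± 0.25 (adjusted p = 0.0337), and Uqcrb of complex III by -1.15 ± 0.19 (adjusted p = 0.0375). After quantile normalization these 4 stood at -0.76, -0.44, -0.78 and -0.22, and none passed.

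Fatty acid oxidation genes had a mean of -0.69 and a median of -0.68, negative in 23 of 24 (camera adjusted p = 2.87e-08). With an estimated correlation the adjusted p was 0.409, and after quantile normalization the mean was -0.16 (adjusted p = 0.38). Over all features 0 passed, and 7 passed when adjusted over the list alone. Pdk4, the kinase that shuts off pyruvate dehydrogenase, stood at -1.72 ± 0.35 (adjusted p = 0.0721), Hadhb of the trifunctional protein at -1.04 ± 0.26, Ucp3 at -1.23 ± 0.32 and Eci1 at -0.77 ± 0.23. With quantile normalization Pdk4 and Ucp3 stood at -1.04 and -1.13, and Hadhb and Eci1 at -0.27 and -0.10. Genes of the TCA cycle and pyruvate dehydrogenase had a mean of -0.73 and a median of -0.57, negative in 19 of 22 (camera adjusted p = 9.52e-05). They did not pass with an estimated correlation (adjusted p = 0.557), with fry (adjusted p = 0.125) or after quantile normalization (mean -0.18, adjusted p = 0.987). Without the 2 sham arrays with the fewest values, a setting chosen after seeing the data, the TCA list had a mean of -0.63 (adjusted p = 0.226). In this list 1 gene, Dlat, was past the threshold over all features and 9 adjusted over the list alone. Mdh2 stood at -1.13 ± 0.27, Sdha at -1.15 ± 0.29 and Idh3b at -0.90 ± 0.23, and with quantile normalization the 3 genes stood at -0.22, -0.38 and -0.10.

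Proteins of the cytosolic ribosome moved alongside the mitochondrial lists, with a mean of -0.69 and a median of -0.75, negative in 42 of 48 (camera adjusted p = 3.07e-13). The call was lost with an estimated correlation (adjusted p = 0.439), with fry (adjusted p = 0.0631) and after quantile normalization (mean -0.0011, adjusted p = 0.864), and the mean was 0.015 after loess. Of the 48 genes, 1 passed over all features and 23 adjusted over the list alone. Rplp1 fell by 1.45 ± 0.25 (SE, adjusted p = 0.0462), and Rps7, Rpl10 and Rplp2 stood at -1.19 ± 0.22, -1.74 ± 0.36 and -1.76 ± 0.38 (adjusted p = 0.0518, 0.073 and 0.0814). For Rpl10 the 2 of 3 probes complete on 8 arrays gave -1.19 ± 0.22. After quantile normalization Rplp1 stood at -0.60 and did not pass (adjusted p = 0.454), and Rps7, Rpl10 and Rplp2 were at -0.67, -1.05 and -0.98.

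The loss of these calls went with signal level. The 354 features with a mean level over 5 had a median change of -0.90, and the 668 features with a level from 4 to 5 had -0.62, whereas quantile normalization left -0.07 and 0.02. The median change of all features was -0.08. The 99th percentile of the log2 signals was 5.65 to 6.31 on the 4 sham arrays and 5.05 to 5.24 on the 4 infarcted arrays.

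**Figure D2:**
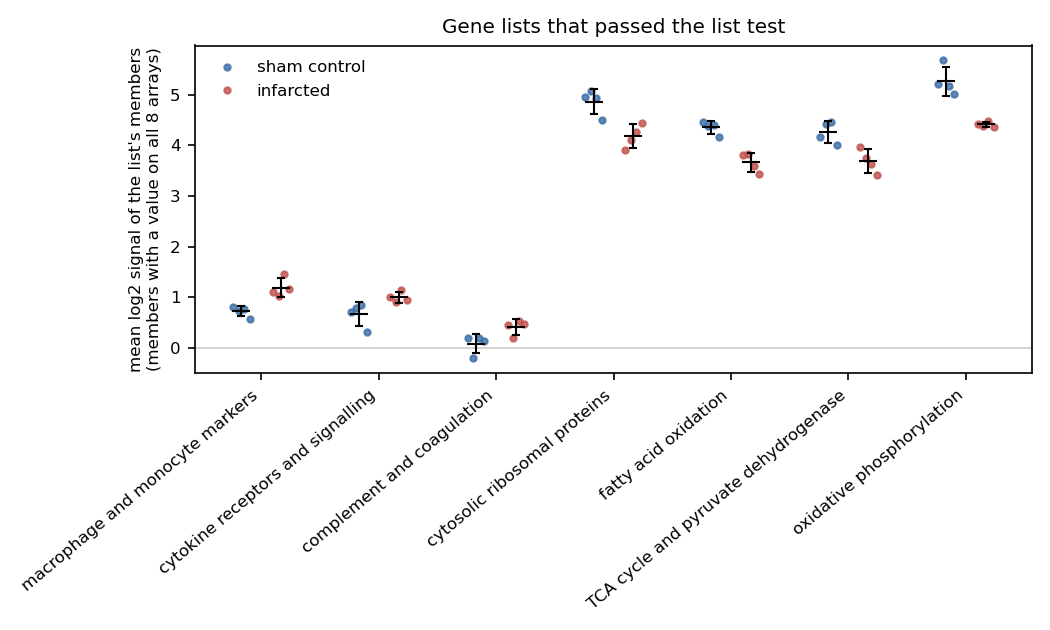
Mean log2 signal of the members of each of the 7 gene lists that passed the list test (y axis; members with a value on all 8 arrays), with a point per array (blue, sham control; red, infarcted; n = 4 each) and bars for the mean ± SD. The 3 immune lists lie higher and the 4 lists of metabolism and ribosome lower in infarcted hearts, with oxidative phosphorylation at 5.27 against 4.42.

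**Figure D3:**
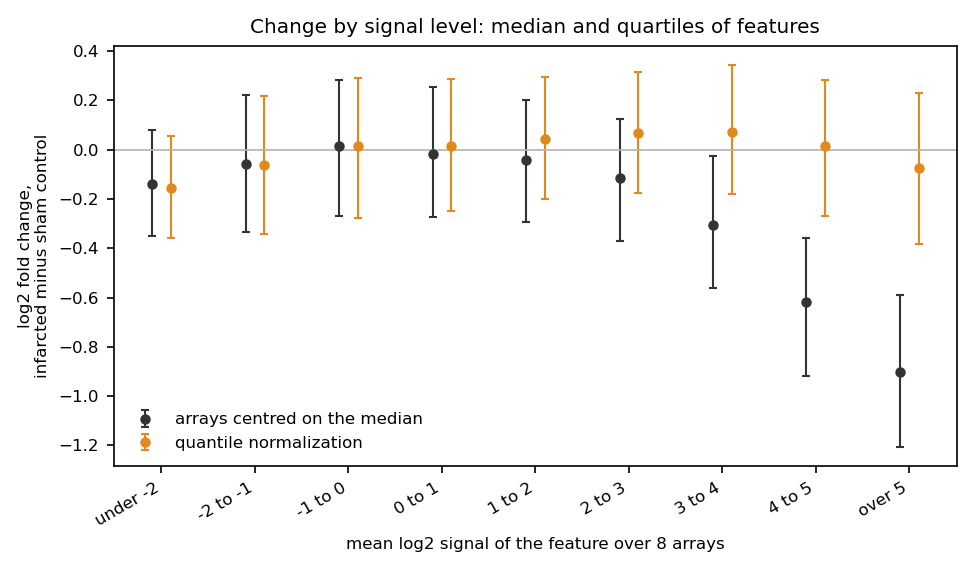
Log2 fold change, infarcted minus sham control (y axis), of all 18044 features by their mean log2 signal over 8 arrays (x axis), as median (point) and quartiles (bars) of the features in each class. With arrays centred on the median (black) the median falls to -0.90 above a level of 5, and after quantile normalization (orange) it is -0.07 there.

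Classical markers of cardiac stress and fibrosis did not pass singly. The natriuretic peptide genes Nppb and Nppa stood at 0.91 ± 0.29 (SE, adjusted p = 0.225) and 0.88 ± 0.68 (adjusted p = 0.665), Postn, a matrix protein of activated fibroblasts, at 1.76 ± 0.54 (adjusted p = 0.209), and Timp1 at 0.66 ± 0.30 (adjusted p = 0.425). After quantile normalization Nppb stood at 1.53 ± 0.26 (adjusted p = 0.068) and Nppa at 1.59 ± 0.66 (adjusted p = 0.471), and Nppa changed by 0.24 without sham control replicate 1. The collagens Col1a1 and Col3a1 stood at -1.27 ± 0.64 and -0.61 ± 0.22 (adjusted p = 0.466 and 0.293), and Ccl2 at -0.35 ± 0.29 (adjusted p = 0.693). Col1a1 had a level of 0.06 on infarcted replicate 1 and 2.32 to 3.55 on the other infarcted arrays, and its change was -0.59 without that array. Col3a1 stood at -0.15 ± 0.24 after quantile normalization. Myh7, the beta myosin heavy chain, had 1.79 ± 0.75 (adjusted p = 0.373), but 2 of its probes were higher and 2 lower, and its 1 probe complete on 8 arrays gave 0.31 ± 0.55. Its level was 0.71 on sham control replicate 1 and 3.74 to 5.08 on the other sham arrays. Gapdh was -0.87 ± 0.26 (adjusted p = 0.194), with 24 probes lower and 2 higher, and its change was -0.05 after quantile normalization and 0.08 after loess. Of the fixed genes, Tgfb1, Il6, Tnf and Il1b had too few values for the main test, which needs 3 in each group, and Myh6 and Acta1 were not analysed here. Atp2a2, the calcium pump of the sarcoplasmic reticulum, had a level of 6.65 ± 0.02 on 4 infarcted arrays, a mean signal of 42402.5 where the highest signal of any array was 65466, and no value on any sham array. The missing values do not show a lower level in sham hearts, since bright spots lacked values mainly on sham arrays.

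The other 33 tested lists did not pass the camera test, which compares the moderated statistics of a list with those of all other features. Its direction was upward for the fibroblast, lymphocyte, hypertrophy and cell cycle lists, whose mean fold changes were below 0. For heart muscle the mean was 0.13 for the fetal and stress programme (median -0.22, adjusted p = 0.68), -0.42 for the adult sarcomere (adjusted p = 0.142) and -0.22 for calcium handling (adjusted p = 0.488). After quantile normalization the direction of the last 2 turned, with means of 0.22 and 0.14 and no call (adjusted p = 0.125 and 0.364). The sarcomere list rested on 12 of its 19 genes on the array and calcium handling on 13 of 15, and 6 and 1 of the untested genes had a signal over 20000 on at least 1 array. Among all features with such a signal 155 values were missing on sham arrays and 34 on infarcted arrays. It was -0.17 for ion channels and conduction (adjusted p = 0.68) and -0.01 for hypertrophy signalling (adjusted p = 0.471). Cytoskeleton and adhesion genes, which include Actb, had -0.12 (adjusted p = 0.713), and atrial markers 0.26 (median 0.02, adjusted p = 0.355). The fetal and stress programme passed after quantile normalization with a mean of 0.59 (adjusted p = 0.0281), passed in 2 of 25 settings, and had a mean of -0.03 without sham control replicate 1. Hypertrophy signalling and the cytoskeleton list turned to 0.08 and 0.09 with quantile normalization and did not pass. For the matrix the mean was 0.19 for fibrillar matrix and fibrosis (adjusted p = 0.0663) and -0.14 for the basement membrane (adjusted p = 0.564; 0.02 without infarcted replicate 3). Matrix proteases and inhibitors had 0.10 (adjusted p = 0.263), and genes of TGF-beta and BMP signalling 0.04 (median -0.03, adjusted p = 0.263). The fibrillar matrix list passed after quantile normalization with 0.34 (adjusted p = 0.00807), and in 10 of 25 settings in all.

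Markers of other cells gave means of -0.12 for fibroblasts and myofibroblasts (adjusted p = 0.89; 0.06 after quantile normalization), -0.02 for lymphocytes (median 0.04, adjusted p = 0.743) and 0.27 for neutrophils and mast cells (adjusted p = 0.0955). Over 25 settings the lymphocyte mean ran from -0.32 to 0.08 and the neutrophil and mast cell mean from 0.02 to 0.36, and neither passed. Endothelial markers, which include Ramp2, had -0.45 (median -0.25, adjusted p = 0.0939), and -0.28 over members with a value on all 8 arrays, which leave out Ramp2. The mean was -0.16 for smooth muscle and pericytes (adjusted p = 0.68), -0.32 for erythroid cells (median 0.04, adjusted p = 0.665) and -0.13 for adipocytes (adjusted p = 0.906). It was 0.28 for skeletal muscle (adjusted p = 0.142), -0.47 for lung and airway epithelium (adjusted p = 0.154) and 0.23 for mesothelium and epicardium (adjusted p = 0.132). Skeletal muscle passed among features with a value on all 8 arrays, with 0.72 (camera adjusted p = 0.00458). Without sham control replicate 2 the lung and airway list passed, with a mean of -0.81 (adjusted p = 0.00127). Cytokines and chemokines, of which 21 of 46 on the array could be tested and only Ccl8 passed, had a mean of 0.21 (adjusted p = 0.0832). The interferon response and antigen presentation had -0.20 (adjusted p = 0.235).

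Among the other lists of metabolism and stress the mean was -0.40 for glycolysis and glucose uptake (adjusted p = 0.0838) and -0.17 for mitochondrial regulators and the phosphocreatine system (adjusted p = 0.496). It was 0.01 for the hypoxia response and angiogenesis (adjusted p = 0.368), 0.12 for apoptosis (adjusted p = 0.142) and -0.17 for oxidative stress and antioxidant enzymes (adjusted p = 0.362). Heat shock and the unfolded protein response had -0.12 (adjusted p = 0.743; 0.27 after quantile normalization, adjusted p = 0.00807). Adrenergic, renin-angiotensin and endothelin genes had -0.13 (adjusted p = 0.982) and the cell cycle -0.02 (adjusted p = 0.564). The mean was -0.17 for proteasome and ubiquitin ligases (adjusted p = 0.355) and 0.17 for the circadian clock (adjusted p = 0.218). With quantile normalization the means were 0.02 for glycolysis, 0.17 for mitochondrial regulators, 0.11 for oxidative stress, 0.02 for the cell cycle and 0.16 for the proteasome, so the direction of these 5 turned, and none passed. Among the 8 fits without 1 array, glycolysis passed in 4, fibrillar matrix and endothelial markers in 3 each, and the adult sarcomere, cytokines, skeletal muscle and lung lists in 1 each.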

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

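The tests against signal level, spot position, probe number and the contrast of cell-type lists were chosen after the results had been seen.

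In 12 of 177 groups of 4 values, 1 array lay far from the other 3, where chance alone gives about 5%, and the 12 cases were spread over all 8 arrays. For single genes these were Cox6b1 in infarcted replicate 2 (4.94), Gapdh in infarcted replicate 4 (5.03), Olfr136 in sham control replicate 4 (1.71), Rplp2 in infarcted replicate 1 (3.28), Sfrp2 in sham control replicate 1 (-0.73) and Ucp3 in infarcted replicate 4 (0.13). For list means they were calcium handling in sham control replicate 3 (3.00), matrix proteases and inhibitors in infarcted replicate 3 (1.17), complement and coagulation in sham control replicate 2 (-0.20), lung and airway epithelium in sham control replicate 2 (-0.013), and mesothelium and epicardium in sham control replicate 3 (0.60) and in infarcted replicate 2 (0.37). The lung and airway markers had a mean of 1.34 on the other 3 sham arrays.

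Outside the tested features, 5 features with a signal over 20000 had a value on all 4 infarcted arrays and on no sham array, and 0 showed the opposite. Among the other 34 splits of the 8 arrays the highest number of such bright features, both directions together, was 1. Signals over 60000 numbered 10 to 38 on the sham arrays and 2 to 3 on the infarcted arrays, so a value absent from the sham arrays may have been too bright to be kept, and whether such spots were removed is unknown. The 5 features are no evidence of a higher level in infarcted hearts. Of these 5, the named ones are Cox6a2, Atp2a2, Atp5b and Fabp3, abundant genes of heart muscle, listed after their values were seen. A further 18 less bright features had a value on all infarcted arrays and no sham array, and 21 the reverse. Their sum of 39 was below the 106 reached by another split.

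The 99 changed features were more than any other split of the 8 arrays gave. Only 1 of 35 splits, the real one, reached that number, and the highest other split gave 3. With 35 splits the smallest possible share is 0.0286, so this count does not exclude chance. The other splits mix sham and infarcted arrays, so any difference between the groups would widen their spread and hold their counts down. Of the 99 features, 28 changed at least 4-fold. A difference in scale that depends on signal level is argued against as the whole cause of these 28, since 21 were called again after quantile normalization, whereas this held for 11 of the 71 smaller changes. A difference between the groups in spot position within blocks had an effect (F = 2.37) below the median of the other splits (2.57, highest 4.78). This F covers all features, so it neither shows that a position effect is absent nor speaks for the 28. Of the 28 calls, 22 were kept when the position effect was removed. That argues against position as the whole cause of these 22 only. Besides chance, a difference at single spots between the arrays used for each group stays open. Of the 12 named genes among the 28, 0 had more than 1 probe. At the share of 23.7% among tested genes only 2.84 would have. Infarction and single spots therefore cannot be told apart for these features.

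The lists of oxidative phosphorylation, fatty acid oxidation, the TCA cycle and the cytosolic ribosome were lower together. Their medians lay at the 25, 12.4, 37.2 and 27.9 percentile of random lists of the same signal level. A difference in scale that depends on signal level would give this. The random lists could also draw members of these lists, so a real fall of abundant transcripts could lower them too. A hypothesis of a loss of mitochondrial transcripts after infarction would put oxidative phosphorylation below the ribosomal list. The difference between these lists changed by -0.16 (exact permutation p = 0.371, two-sided), so the explanations cannot be told apart here. For the number of passing lists chance is not excluded: 13 of 35 splits gave at least the 7 lists of the real split, and the highest other split gave 14.

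The lists of macrophage markers and of cytokine receptors were higher. Signal level alone is argued against as the cause, because both medians lay at the 100 percentile of random lists of the same signal level. Lists without a call were also extreme: fibrillar matrix 99.8, heat shock 99.2, mesothelium 98.6, skeletal muscle 98.1, and lung and airway 1.27. The random lists drew features independently, whereas the macrophage and cytokine receptor lists had estimated correlations of 0.089 and 0.155, so their percentiles may overstate. The complement list, also higher, lay at the 91.5 percentile, so signal level is not excluded for it. A lower share of heart muscle cells would raise markers of all other cells alike. Over members complete on 8 arrays, the endothelial, smooth muscle and fibroblast lists changed by -0.28, -0.15 and 0.03. That argues against a lower share as the sole cause of the macrophage rise. The macrophage list rose over their mean by 0.59, from -0.65 ± 0.07 to -0.05 ± 0.30 (SD, n = 4 each, exact permutation p = 0.0286, two-sided, the smallest possible). This p adds little, because the macrophage list was chosen for its rise and separated the groups alone. Over the lymphocyte list alone it rose by 0.52, which did not pass (exact permutation p = 0.0857, two-sided). A hypothesis that stays open is a larger share or an altered state of macrophages in infarcted hearts. The macrophage list's exact p of 0.0286 became 0.163 after adjustment over 40 lists, and the split count above does not exclude chance for list calls in general.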

How the results depend on the processing

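More features were lower than higher in each setting except the replicate block and the fits without infarcted replicate 3 or 4, but the counts varied widely. After quantile normalization 32 features changed (5 higher, 27 lower) and after scale normalization 48 (41 lower). A filter of at least 2 of 4 arrays gave 16 higher. Array weights gave 506 (42 higher, 464 lower), and an unequal-variance (Welch) test with adjustment gave 6 (2 higher, 4 lower). The rules with a fold of 1.5 and an unadjusted p under 0.05 gave 2003 (538 higher, 1465 lower) with limma and 1295 (319 higher, 976 lower) with the Welch test. An adjusted p under 0.10 gave 278 (36 higher, 242 lower), and leaving out the lowest and highest 1% gave 43 (35 lower). Of the settings chosen after seeing the data, a whole-array median gave 27 (4 higher, 23 lower), removal of the position effect 54 lower, a signal minimum of 200 gave 235 (18 higher, 217 lower), and leaving out the 2 sham arrays with the fewest values gave 1132 (43 higher, 1089 lower) and 13 lists. The cause was not tested. Leaving out 1 array gave 3 to 666 changed features, 2 to 28 higher and 1 to 638 lower; fewer arrays leave fewer degrees of freedom, but sham control replicate 4, with the fewest values, raised the count when left out.

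The number of passing lists was 7, and 7 to 10 when 1 array was left out. It was 0 with an estimated correlation, 2 with fry (oxidative phosphorylation and fatty acid oxidation), and 0 with the exact permutation test of list means, where the smallest p over 40 lists cannot reach the threshold for a few lists alone. The heat shock list turned to 0.27 after quantile normalization and 0.30 after loess, and the ribosomal list to 0.015 after loess; the cause was not tested. A further 10 lists without a call changed sign under quantile normalization. Macrophage markers ranged from 0.34 to 0.59 over 25 settings and passed in 22 (adjusted p from 3.54e-07 to 0.409).

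With the replicate number as a block, 1 feature changed (1 higher, 0 lower), and 8 lists passed. The labels do not say that the numbers pair the samples. The correlations of deviations between same-numbered arrays were 0.022, 0.31, -0.077 and -0.19, and 1 of 4 sham arrays correlated best with its own number. These values show no pairing but cannot exclude it. Over the 54 named genes and all settings, 0 called changes reversed sign. Values as deposited gave the same results because their medians were already 0. Cyclic loess between all pairs was not run. For dim spots the depth is limited by the lowest signals, which ranged from 42 to 86 per array.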

Other observations

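Apart from bright spots, 39 features had values on all 4 arrays of 1 group and on none of the other, and another split of the 8 arrays into 4 and 4 reached 106. Why these values are absent is unknown, so they are no evidence of a difference in the hearts. The following 5 were chosen from the 39 after their values were seen. Msln, a marker of mesothelium, and Clec10a, a lectin of macrophages and dendritic cells, had values on all 4 infarcted arrays and on no sham array, at mean log2 levels of 0.077 and 0.076. Cfp, properdin of the complement system, had a mean of 1.68 on all 4 sham arrays and no value on any infarcted array. Foxm1, a transcription factor of proliferating cells, and Foxo4 were likewise valued on the sham arrays alone, near the dim end at -1.74 and -1.94.

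The skeletal muscle list, present to show tissue carried over from the chest wall, had a mean level of -1.02 in sham and -0.30 in infarcted hearts over members with a value on all 8 arrays (exact permutation p = 0.0571, two-sided). Among features with a value on all 8 arrays, the list passed camera with a mean change of 0.72 (adjusted p = 0.00458). The lung and airway list had mean levels of 1.00 in sham and 0.53 in infarcted hearts (exact permutation p = 0.229, two-sided).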
